A study of Homo sapiens with 10 samples.

How the data were processed

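Messenger RNA was measured in CD3+ T cells of human blood from 5 donors, each donor giving 1 resting and 1 stimulated library, so that 10 libraries fell into 2 groups of 5. Per the labels' protocols, the cells were kept in medium with interleukin-2 at 300 U/mL. The stimulated cells had 4 days with beads carrying antibodies against CD3 and CD28, which engage the T cell receptor and its costimulatory receptor, and were taken 1 day after that period. Live CD3+ cells were sorted before RNA extraction in both groups. Per the same protocols, 200 ng of RNA with an integrity number above 7 was enriched for polyadenylated RNA, copied with random primers and sequenced as paired reads of 150 bases on DNA nanoballs. How long the resting cells had been in culture is not given in the sources used here.

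The submitters' processing notes name HISAT, Bowtie2 2.3.4.3, RSEM 1.3.1 and DESeq2 1.4.5 and the genome build hg38, with no role or order. The deposited expected counts were estimated read counts per feature, with an effective length from RSEM beside them per the file headers, and they need not be whole numbers. The deposited TPM values were transcripts per 1e6 transcripts as the authors computed them from those lengths and counts, per the file headers, and served for levels and for alternatives. The deposited FPKM values were not used here. Reads that fit several features are shared between them by RSEM, so a count that is not whole marks a feature with shared reads. With a tolerance of 0.005, 51.7% of the annotated gene IDs had whole counts in all 10 libraries. Strandedness, the annotation release and the trimming were not given in the sources used here, so overlapping and antisense genes could not be told apart.

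The files listed 24543 features, of which 16751 were gene IDs and 7791 were loci assembled from reads without a gene name. Of the gene IDs, 16703 matched a symbol by ID in RefSeq's gene table for GRCh38.p14 and 48 did not. The assembled loci had a median length of 4731 bases against 2935 for gene IDs, and their positions were not used here. A feature missing from a library's file was set to 0. A tagged SLC7A2 construct, with at most 1 count in a library, did not pass the expression filter. XIST, TSIX and Y-linked genes (21 features) were left out of every step. The list of mitochondrially encoded transcripts was void, since 0 of its members were listed, and TRAC, TRBC1 and TRBC2 were not listed either. Total expected counts, in units of 1e6, were 14.98 to 15.78 per resting library and 18.66 to 19.21 per stimulated library, so that 3 counts, the floor used for a value of 0, stand for 0.156 to 0.2 CPM in one library. Floors for folds were taken as 3 counts over all libraries of a group. Floors and the intervals called counting intervals cover counting error only, and the reads carried no molecular identifiers. The interval of the SLC7A1 fold is from the standard error of the fit and so reflects the spread between libraries.

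Expected counts were rounded to whole numbers and tested for stimulated minus resting with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, estimateDisp, glmQLFit and the two-sided glmQLFTest), with Benjamini-Hochberg adjustment over all features tested and a threshold of 0.05. Every adjusted p of a gene in the text is from this test unless another is named. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values are TMM-scaled, and errors beside levels are SDs over 5 libraries. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided and adjusted over 25 lists, against annotated genes only, since no assembled locus could be a list member. This restriction was set after the assembled loci were seen, and the wider background is an alternative. Members of lists were also adjusted over the list alone. This gave 39 rather than 38 higher interferon-stimulated genes and the same counts in every other list. The solute carrier list was taken by the pattern of the symbol. It so also holds genes that are not transporters, such as SLC2A4RG, SLC7A6OS and SLC4A1AP, and SLC71A3P, which is named like a pseudogene.

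The rule for named genes took SLC7A1, every tested member of the cGAMP transport and cGAS-STING lists, up to 3 members of each other list in its more frequent direction and 1 in the other, by size of change among those past the threshold with the same sign in all 5 donor pairs and at least 5 CPM in a group, and the 10 largest increases and decreases over all genes with at least 10 CPM in a group. T cell receptor, immunoglobulin, HLA and KIR genes, genes with common whole-gene deletions, pseudogenes and unnamed loci were left out of its last parts. Some of the genes it took are not reported here. It gave 137 genes, of which 65 had whole counts in all 10 libraries. The design, the lists, this rule and the alternatives below, save those named as added, were fixed before the data were examined.

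The donor numbers in the labels pair the libraries across groups. Over 9662 annotated genes, deviations from the group mean correlated at 0.209 to 0.323 between the 2 libraries of a donor and at -0.186 to 0.036 between libraries of different donors. The fit without pairing was kept as planned, and the fit with the donor number as a replicate block was an alternative. No 2 libraries were alike within sampling noise. Other alternatives were RLE and upper-quartile factors and total counts in place of TMM, no filter or a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), each library and each donor left out, a minimum log2 fold change of 1 in edgeR's glmTreat, camera with an estimated correlation, and fry. Added after the data were seen were fits of annotated genes alone, fits of whole-count genes alone, the background with assembled loci, and the permutation of SLC7A1 within donor pairs.

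The fits were tested on simulated data drawn from the real means, dispersions and library sizes, with 200 genes changed. Over 18109 features, the edgeR step recovered 15.2% of genes changed 1.5-fold, 54% of those changed 2-fold, 85.1% of those changed 4-fold and 85.7% of those changed 8-fold, and called 8 of 17892 unchanged features. Camera found the 1 list that had been changed 2-fold and called 0 of the other 24 in this simulation. Genes were drawn independently there, whereas the estimated correlation in the data reached 0.786 for interferon-stimulated genes. Nor did the simulated groups differ in the share of assembled loci. False calls of correlated lists and errors of scaling were therefore not tested by it. Far fewer features were changed there than the 80.7% that passed in the data. The adjustment was thus stricter in the simulation, and its recovery rates do not give those of the data.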

Results

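The libraries compared resting human CD3+ T cells with cells of the same 5 donors taken 1 day after 4 days of stimulation through CD3 and CD28. The series title names induction of SLC7A1 by activation and sensitivity to cGAMP, the cyclic dinucleotide that binds STING, as the question behind the comparison. Total expected counts, in units of 1e6, were 15.3 ± 0.308 in resting and 18.9 ± 0.238 in stimulated libraries (SD, n = 5 each). Loci assembled without a gene name held 25.04% ± 1.57 of the counts of resting libraries and 7.69% ± 0.31 of those of stimulated libraries.

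SLC7A1, which encodes a plasma membrane transporter of arginine and other cationic amino acids, was higher in the stimulated library of all 5 donors. Its level was 8.42 TPM ± 0.691 in resting and 42.5 TPM ± 4.19 in stimulated cells (SD, n = 5 each), or 33.8 CPM ± 2.36 and 230 CPM ± 22.3. The log2 fold change was 2.76 ± 0.0904 (SE), a 6.78-fold increase with a 95% interval of 6 to 7.67, and edgeR's adjusted p was 5.68e-10. The exact two-sided permutation p was 0.00794, the smallest that 252 assignments of the 10 libraries can give. These assignments leave out the pairing by donor, and exchange within the 5 pairs gave 0.0625, the smallest that its 32 assignments can give. The gene lies on chromosome 13 from 29509414 to 29595688 (GRCh38.p14), and its counts were not whole in any library, so an unknown part of its reads was shared with other features. The size of the change depended on scaling. The ratio of mean TPM was 5.04, and the log2 fold change was 2.14 when assembled loci were removed before scaling.

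**Figure D1:**
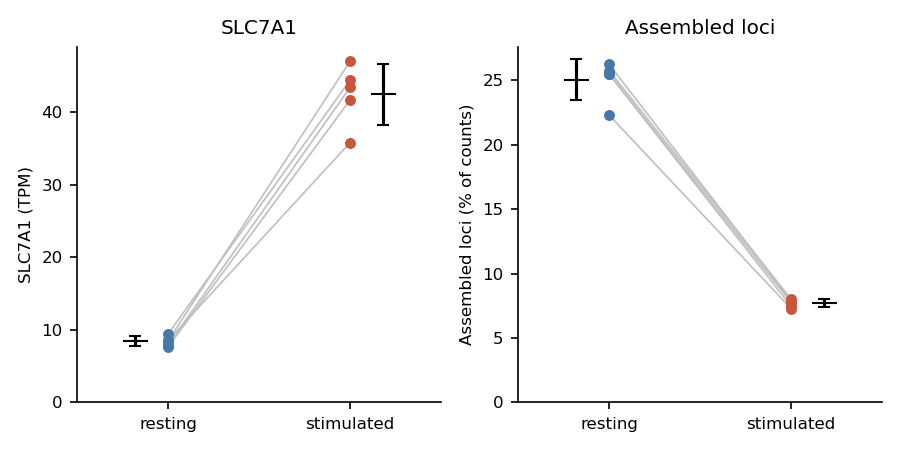
SLC7A1 in TPM (left) and the share of counts in assembled loci in percent (right) for each library, with grey lines joining the 2 libraries of a donor and black bars showing the mean ± SD (n = 5). SLC7A1 was near 8.42 TPM in resting and 42.5 TPM in stimulated libraries, and the assembled share was 25.04% and 7.69%.

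Among 226 solute carrier genes tested, 116 were higher in stimulated cells, 54 were lower and 56 did not pass, and as a list they did not stand apart from other genes (camera adjusted p = 0.841; 0.947 with an estimated correlation). With assembled loci removed before scaling, 98 were higher and 88 lower, and the list's median turned from 0.57 to -0.05. SLC7A1 ranked 28th of these genes by fold change and 35th by TPM in stimulated cells, against 91st by TPM in resting cells. The largest increases with the rule's expression minimum were in SLC16A9 and SLC6A9, which had 1 and 2 counts over all resting libraries and were 422-fold (95% counting interval 75.3 to 16700) and 280-fold (77.1 to 2310) higher, and in SLCO4A1, which rose from 0.344 to 83.6 CPM. SLC14A1, a urea transporter, fell by 3.76 ± 0.322 on the log2 scale.

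Of 25 amino acid transporters tested, 15 were higher, 3 were lower and 7 did not pass, and with assembled loci removed before scaling 15 were higher and 7 lower. The list did not stand apart from other annotated genes (adjusted p = 0.206; 0.232 with an estimated correlation). SLC1A5, the glutamine transporter ASCT2, rose from 11.2 to 438 CPM (log2 fold change 5.28 ± 0.273), and SLC7A11, the cystine transporter, from 0.214 to 5.74 CPM (4.69 ± 0.321). SLC7A6 fell from 193 to 91.6 CPM. SLC7A5 and SLC3A2, the chains of the transporter LAT1 and named here after their values were seen, had log2 fold changes of 3.33 ± 0.368 and 1.49 ± 0.11. In resting replicate 5, SLC1A5 was at 20.1 CPM against 7.22 to 10.6 in the other resting libraries.

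**Figure D2:**
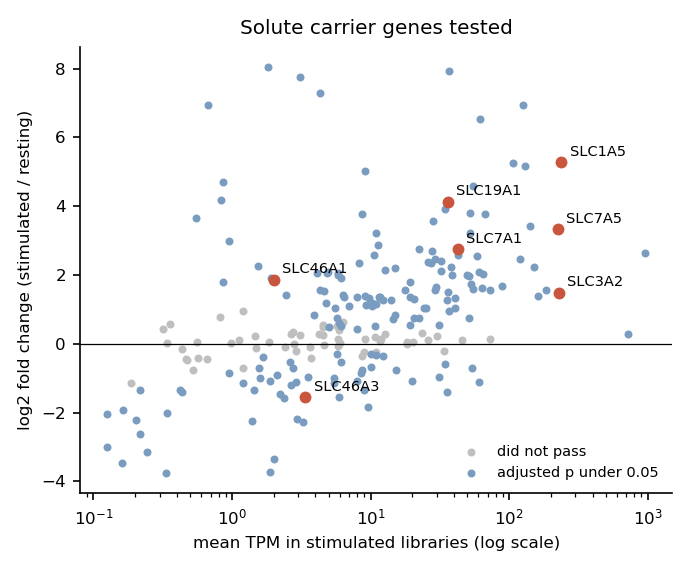
Log2 fold change of 226 solute carrier genes against their mean TPM in stimulated libraries on a log axis (n = 5 per group), blue where the adjusted p was under 0.05 and with 7 transporters of amino acids or folates or of the SLC46 family in red. SLC7A1 lay at 2.76 and 42.5 TPM, below SLC19A1, SLC7A5 and SLC1A5 in fold change.

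Genes for the passage of cGAMP across membranes and for its hydrolysis moved in both directions. Of 11 tested members, 6 were higher, 3 were lower and 2 did not pass. The importer SLC19A1, the reduced folate carrier, rose from 5.06 CPM ± 0.771 to 88.8 CPM ± 6.67 (SD, n = 5 each; log2 fold change 4.13 ± 0.12, adjusted p = 3.14e-10), with whole counts in all 10 libraries. SLC46A1, the proton-coupled folate transporter, rose by 1.86 ± 0.278 and ENPP1, the ectoenzyme that hydrolyses cGAMP, by 1.90 ± 0.299, the latter from 0.495 to 1.87 CPM. GJB2, a gap junction protein, had 0 counts in every resting library and 44.0 CPM ± 28.5 in stimulated cells, at least 1220-fold higher. SLC46A3 fell by 1.55 ± 0.179, the ATP-gated channel P2RX7 by 1.24 ± 0.159, and LRRC8C, a subunit of volume-regulated anion channels, by 0.47 ± 0.118.

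The calls of the other members of this list depended on scaling. ABCC1, an exporter, had a log2 fold change of 0.58 ± 0.131 and LRRC8B one of 0.32 ± 0.119, and both were below 0 when assembled loci were removed before scaling (-0.03 and -0.30). There ABCC1 did not pass (adjusted p = 0.809) and LRRC8B passed as lower (0.0383). The call of LRRC8B as higher was also lost without resting replicate 2 (adjusted p = 0.0503) and without stimulated replicate 2 (0.0629). LRRC8D and LRRC8A had log2 fold changes of 0.16 ± 0.14 and 0.02 ± 0.0736 and did not pass. LRRC8D passed without resting replicate 5 (log2 fold change 0.30, adjusted p = 0.0176), and with assembled loci removed it passed as lower (-0.46, adjusted p = 0.00483). LRRC8A passed as lower with assembled loci removed (-0.60, adjusted p = 1.34e-05), with upper-quartile factors (0.0329), with total counts (0.00904) and with TPM (0.000519 for a pseudocount of 1). As a list these genes did not stand apart (adjusted p = 0.985; 0.988 with an estimated correlation), and with assembled loci removed 4 were higher and 6 lower and the median turned from 0.32 to -0.30.

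In the cGAS-STING pathway, which senses cytosolic DNA, 23 of 32 tested genes were higher, 3 were lower and 6 did not pass. The sensor CGAS rose from 11.5 CPM ± 3.08 to 41.9 CPM ± 13.4 (log2 fold change 1.87 ± 0.252, adjusted p = 3.08e-05), IFI16, another DNA sensor, by 2.00 ± 0.104, and IRF7, an interferon transcription factor, by 2.86 ± 0.42. The DNA exonuclease TREX1 rose by 2.27 ± 0.206 and RNASEH2A, the catalytic subunit of RNase H2, by 4.35 ± 0.254. AP1S1, SEC24C and SURF4, which act in vesicle transport, rose by 2.57, 1.74 and 1.65, and ENDOD1, NLRX1, NFKB1, IFNAR1, RNF5 and RNASEH2B rose by between 1.34 and 1.88. NLRC3 fell from 271 to 109 CPM (log2 fold change -1.32 ± 0.0969), STIM1, a calcium sensor that retains STING in the endoplasmic reticulum, by 0.52 ± 0.13, and RNASEH2C by 0.57 ± 0.119.

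The level of STING1 was 119 CPM ± 20.9 in resting and 197 CPM ± 75.2 in stimulated cells, with a log2 fold change of 0.72 ± 0.243 and an adjusted p of 0.0167. The paired fits with a replicate block kept the call, at 0.66 ± 0.15 in edgeR (adjusted p = 0.00446) and 0.66 ± 0.162 in DESeq2 (8.15e-05). Without pairing, the call was lost with upper-quartile scaling (adjusted p = 0.0736), with total counts (0.118) and with TPM (0.406 for a pseudocount of 1). It was also lost with assembled loci removed (0.673) and without both libraries of replicate 1 (0.0648) or of replicate 6 (0.0514). TRIM56 (0.63 ± 0.213) lost its call under the same settings. TRIM32, STEEP1, DNASE2, TBK1, TOLLIP, IRF3 and ZDHHC3 had log2 fold changes between 0.42 and 0.86 that passed the test, and none of them was past the threshold in that direction when assembled loci were removed. ZDHHC3 was then past it in the other direction, at -0.20. IFNAR2 (-0.50), RELA (0.16), USP20 (-0.17), ZDHHC7 (0.08) and IKBKE (-0.04) did not pass. With assembled loci removed, IFNAR2 (-1.11), USP20 (-0.79) and IKBKE (-0.65) passed as lower, and so did RELA (-0.46) and ZDHHC7 (-0.54), with the opposite sign. SAMHD1 had a log2 fold change of 0.39 ± 0.214 and an adjusted p of 0.116, which was 0.0482 in the paired fit with a replicate block. Over the alternatives its log2 fold change ran from -0.23 to 0.57, so its sign was not stable. Without stimulated replicate 7, IFNAR2 (-0.68, adjusted p = 0.0129) and USP20 (-0.24, 0.0478) passed. Both also passed as lower with upper-quartile factors (adjusted p = 0.0216 for IFNAR2 and 0.0161 for USP20) and with total counts (0.0131 and 0.00565). The same held with TPM (0.00275 and 0.000364 for a pseudocount of 1). IFNAR2 passed as well with the filter at 5 CPM (0.042) and with limma-voom (0.0474). RELA passed without resting replicate 1 (0.20, 0.0445), and SAMHD1 without resting replicate 5 (0.57, 0.0196) or stimulated replicate 2 (0.51, 0.0456). The list did not stand apart from other annotated genes (adjusted p = 0.557; 0.881 with an estimated correlation), and with assembled loci removed 14 were higher, 9 lower and 9 did not pass. Its median log2 fold change was 0.77, and -0.10 in a separate fit of whole-count genes, which held 10 of its members and shifted fold changes by -0.777 through its own scaling.

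**Figure D3:**
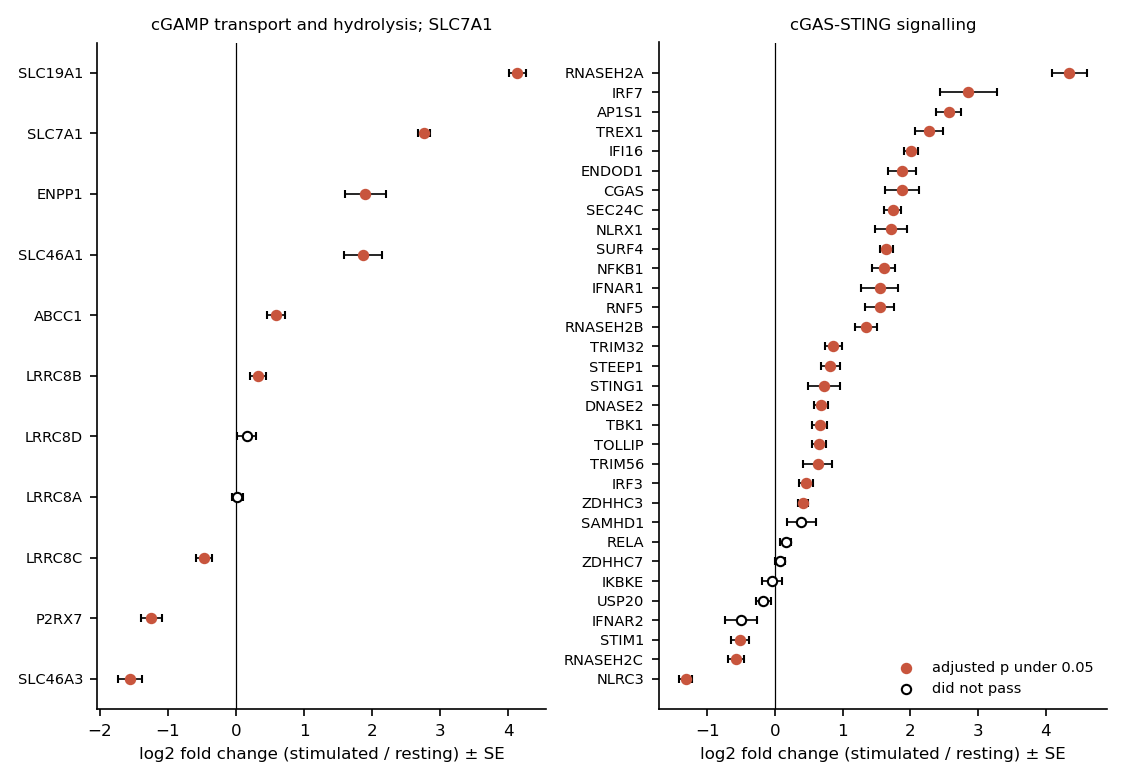
Log2 fold change ± SE (stimulated over resting, n = 5 per group) of SLC7A1 and the cGAMP transport and hydrolysis genes (left) and of cGAS-STING genes (right), with open circles for genes that did not pass. SLC19A1 lay at 4.13 and SLC7A1 at 2.76, CGAS at 1.87 and STING1 at 0.72, and GJB2 is not drawn because its resting counts were 0. With assembled loci removed before scaling, ABCC1, LRRC8A, LRRC8B, LRRC8D, IRF3, RELA, ZDHHC3 and ZDHHC7 turned below 0. SAMHD1, which did not pass, reached -0.23 at its lowest over the alternatives.

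Interferon-stimulated genes were mostly higher after stimulation. Of 42 tested members, 38 were higher, 1 was lower and 3 did not pass (39 higher when adjusted over the list alone), with a median log2 fold change of 2.84. CXCL10, a chemokine, had 0 counts in every resting library and 22.1 CPM ± 18.6 in stimulated cells, at least 622-fold higher. IFI44L rose from 0.37 to 114 CPM and IFI27 from 0.243 CPM to 20.2 CPM ± 24.9, while TRIM22 fell by 0.49 ± 0.14. The spread between donors was wide, and the IFI27 mean rested largely on stimulated replicate 1, at 60.2 CPM, and the resting mean of IFI44L on resting replicate 1, at 0.904 CPM. The list did not stand apart from other annotated genes in the unpaired test (adjusted p = 0.206; 0.914 with an estimated correlation), and it did in the paired test with a replicate block (0.0395), without stimulated replicate 2 (0.0432) and without stimulated replicate 7 (0.0129). It also did with DESeq2 (0.0243), with no expression filter (0.0218), with TPM (0.00253 for a pseudocount of 1) and with assembled loci removed before scaling (0.0276). All these passing fits used the preset correlation of 0.01, whereas the correlation estimated for this list was 0.786.

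Across all features, 7226 were higher and 7590 lower in stimulated cells and 3537 did not pass, of 18353 tested. At least 2-fold changes were called for 5311 features upward and 6039 downward. Assembled loci accounted for 4401 of the lower and 696 of the higher features. Among 11905 annotated genes, 6530 were higher and 3189 lower, and their median log2 fold change was 0.607. This split depended on scaling. With assembled loci removed before scaling, 4812 annotated genes were higher and 4866 lower, and fold changes shifted by -0.617 on the log2 scale. The shift was -0.209 with upper-quartile factors, -0.273 with total counts and -0.417 with log2(TPM + 1), which called 5495 annotated genes higher and 4117 lower. Changes smaller than these shifts are therefore relative to the scaling.

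Most genes of cell division and of biosynthesis were higher in stimulated cells, and the medians of their lists stayed above 0 under each scaling run here. All 66 cell cycle and DNA replication genes were higher, with a median log2 fold change of 6.57 (camera adjusted p = 1.86e-51; 0.00566 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, rose from 0.659 to 369 CPM, the mitotic kinesin KIF20A from 0.152 to 87.7 CPM and cyclin A2 (CCNA2) from 0.447 to 197 CPM. All 41 ribosome biogenesis genes were higher, among them BYSL (5.29 ± 0.239), MRTO4 (4.70 ± 0.368) and NOP16 (4.29 ± 0.169). Their list passed with the preset correlation (adjusted p = 6.22e-14) and not with an estimated one (adjusted p = 0.188). Of 34 serine, one-carbon and nucleotide synthesis genes, 33 were higher and 1 did not pass (3.09e-15; 0.0462 with an estimated correlation). TYMS rose by 7.91, the ribonucleotide reductase subunit RRM2 by 7.90 and PSAT1, of serine synthesis, by 6.55.

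Energy and lipid metabolism moved the same way. Of 25 glycolysis genes 23 were higher and 1 was lower (adjusted p = 2.24e-12; 0.0251 with an estimated correlation). Hexokinase 2 (HK2) rose by 4.86 ± 0.168, the enolase ENO1 from 312 to 5553 CPM and PGAM1 by 3.97 ± 0.124, whereas the glucose transporter SLC2A3 fell by 1.11 ± 0.199. Of 42 nuclear oxidative phosphorylation genes 41 were higher and 0 lower (2.2e-13; 0.0408 with an estimated correlation), with NDUFA8, NDUFAB1 and ATP5MC1 at log2 fold changes of 3.17, 3.14 and 3.09. All 32 cholesterol and fatty acid synthesis genes were higher (3.19e-08; 0.0251 with an estimated correlation), including the desaturases SCD (7.76 ± 0.227) and FADS2 (4.82 ± 0.757). In resting replicate 5, FADS2 was at 32.5 CPM against 2.26 to 6.51 in the other resting libraries, ENO1 at 384 against 283 to 310 CPM and NDUFA8 at 9.21 against 3.33 to 4.9 CPM.

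Of 27 arginine and polyamine genes 22 were higher and 3 lower (adjusted p = 0.00147; 0.0497 with an estimated correlation). PYCR1, of proline synthesis, rose from 0.488 to 103 CPM, the arginase ARG2 from 0.0815 to 10.5 CPM and the nitric oxide synthase NOS3 from 0.12 to 7.09 CPM, and SAT1, of polyamine breakdown, fell from 134 CPM ± 16.9 to 54.5 CPM ± 20.9. The resting means of ARG2 and NOS3 rest on 7 and 10 counts, largely from resting replicate 6 (0.245 CPM) and resting replicate 7 (0.304 CPM). In the amino acid starvation list, whose genes respond to ATF4, 28 of 30 were higher and 1 was lower (2.73e-06; 0.0497 with an estimated correlation). CBS rose from 0.0463 to 30.2 CPM and STC2 from 0.125 to 20.6 CPM, with resting means that rest on 4 and 11 counts, the most in resting replicate 5. DDIT3, which encodes CHOP, fell by 1.01 ± 0.283. AARS1 had a log2 fold change of 7.77 ± 0.959, but 4 of its resting libraries were at 0 and resting replicate 5 was at 4.01 CPM, and its counts were whole in 4 libraries only, so its fold is uncertain. Of 34 unfolded protein response and chaperone genes 26 were higher and 4 lower (0.00603; adjusted p = 0.504 with an estimated correlation), among them the chaperonins HSPE1 and HSPD1 (4.21 and 4.19) and HSPH1 (3.98). ERN1, the stress sensor IRE1, fell by 3.10 ± 0.221. The list's call was also lost among whole-count genes alone (adjusted p = 0.144).

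Of 44 activation and effector genes 29 were higher, 9 were lower and 6 did not pass, and the list did not stand apart from other genes (adjusted p = 0.805; 0.947 with an estimated correlation). The transcription factor BATF3 rose from 0.269 to 132 CPM. IL9 and IL5, type 2 cytokines, had 0 counts in every resting library and were at least 901-fold and 213-fold higher, with levels of 32.6 CPM ± 45.1 and 7.68 CPM ± 8.64 that were set largely by stimulated replicate 5. NR4A2, an early target of T cell receptor signalling, fell by 6.22 ± 0.614. Of 35 apoptosis genes 18 were higher and 11 lower (0.941; 0.975 with an estimated correlation), and with assembled loci removed 15 were higher and 16 lower. BIRC5, which encodes survivin, rose by 7.56 ± 0.298, TNFSF10, the ligand TRAIL, by 3.17 ± 0.434, and its receptor TNFRSF10A fell by 2.97 ± 0.229.

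Genes of naive and quiescent T cells fell. Of 34 members 27 were lower, 2 were higher and 5 did not pass (adjusted p = 3.39e-13; 0.0408 with an estimated correlation). TXNIP fell from 2493 to 88.2 CPM, TSC22D3, which encodes the glucocorticoid-induced leucine zipper, from 1112 to 20.5 CPM and PIK3IP1 from 507 to 12.3 CPM, and ACTN1 rose by 2.40 ± 0.331. Of 27 T cell identity genes 6 were higher, 11 were lower and 10 did not pass, and with assembled loci removed 2 were higher and 20 lower. The list stood lower than other genes with the preset correlation (0.00248) and not with an estimated one (adjusted p = 0.158). The transcription factor BCL11B fell by 2.21 ± 0.1, RUNX3 by 1.62 ± 0.238 and the kinase FYN by 1.51 ± 0.137. SH2D1A had a log2 fold change of 4.53 ± 1.01, with resting replicate 5 at 17 CPM against 0.181 to 0.73 in the others, and its counts were whole in no library. CD4 (0.12) and CD8A (-0.48), named after their values were seen, did not pass. Of 20 inhibitory receptor and exhaustion genes 7 were higher and 9 lower (0.102; 0.188 with an estimated correlation), with a median of -0.18. It was 0.54 in the separate fit of whole-count genes, where both the scaling and the members (10) differed, and -0.80 over all 20 with assembled loci removed. CISH rose from 24.2 to 337 CPM, while KLRG1 fell by 4.52 ± 0.288, SOCS3 by 2.31 ± 0.258 and VSIR by 2.15 ± 0.24.

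Early-response and stress genes were mostly lower in stimulated cells, with 20 of 29 lower, 6 higher and 3 not passing. The list stood lower with the preset correlation (adjusted p = 3.19e-08) and not with an estimated one (adjusted p = 0.188). JUN fell from 1374 to 36.4 CPM, the phosphatase DUSP1 by 5.33 ± 0.271 and ZFP36, an RNA-binding protein of mRNA decay, by 4.55 ± 0.322, and the heat shock gene HSPA1A rose by 3.82 ± 0.291. Replication-dependent histone transcripts, most of which lack a poly(A) tail and so escape this enrichment, were lower for 11 of 15 tested genes and higher for 0 (0.000373; adjusted p = 0.158 with an estimated correlation). H2BC21 fell from 29.3 to 0.478 CPM, H2AC18 by 3.75 ± 0.221 and H1-2 by 1.45 ± 0.301.

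**Figure D4:**
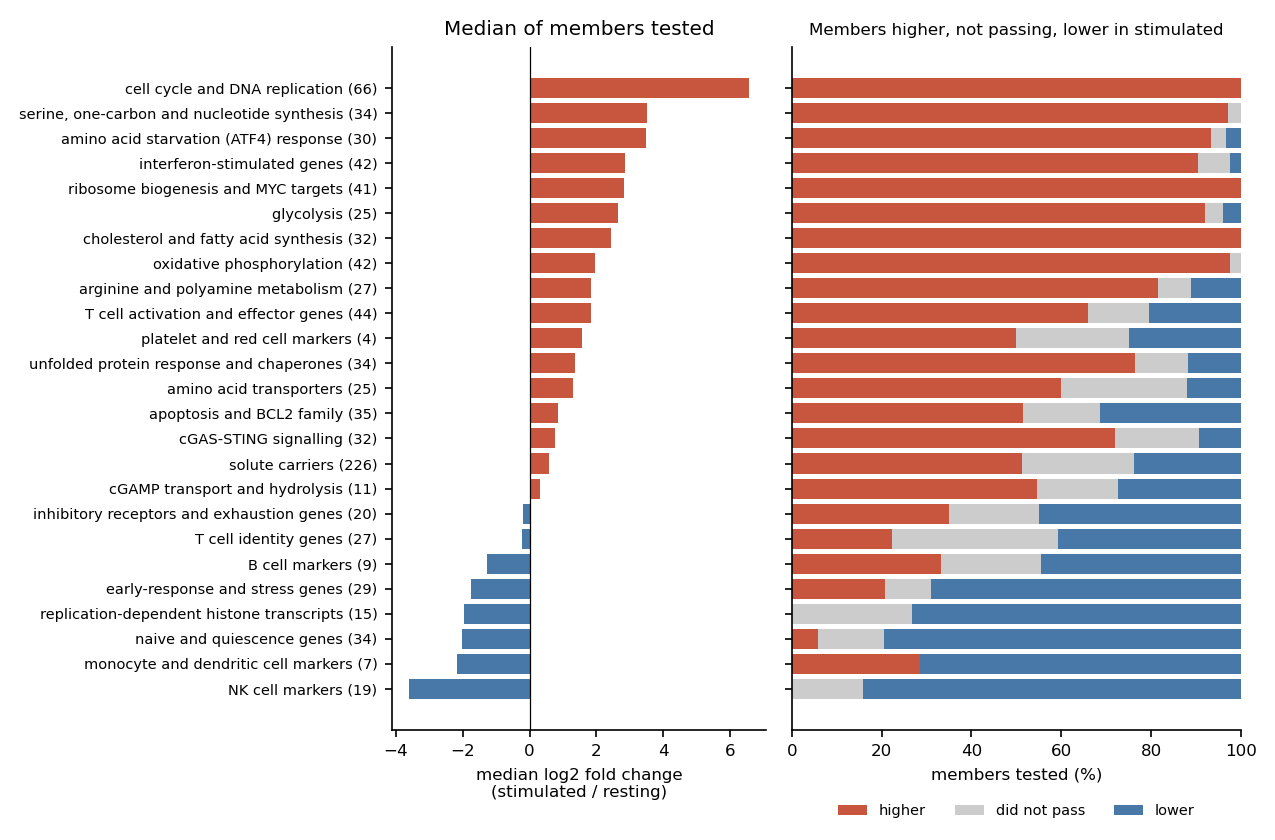
Median log2 fold change of the tested members of 25 gene lists (left, number of members in brackets) and the percentage of members that were higher, did not pass or were lower in stimulated cells (right; n = 5 libraries per group). Cell cycle genes had the highest median (6.57) and NK cell markers the lowest (-3.60), and the medians of the cGAMP and solute carrier lists lay below 0 with assembled loci removed before scaling, while in a separate fit of whole-count genes with its own scaling and fewer members that of the cGAS-STING list lay below 0 and that of the inhibitory receptor list above 0.

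Markers of natural killer cells fell although both groups had been sorted for CD3. Of 19 tested markers 16 were lower and 3 did not pass, with the preset correlation (adjusted p = 6.27e-05) and not with an estimated one (adjusted p = 0.209). FCGR3A, the Fc receptor CD16, fell from 44.4 CPM ± 30.8 to 0.399 CPM ± 0.444, the latter largely from stimulated replicates 5 and 7, and S1PR5 by 5.84 ± 0.377. KLRF1 had 3 counts over all stimulated libraries, a ratio of 0.00196 to resting (95% counting interval 0.000404 to 0.00574). T cells also express several genes of this list. Of 7 monocyte and dendritic cell markers 5 were lower and 2 were higher (0.254; 0.325 with an estimated correlation), with TYROBP and the integrin ITGAM down by 4.71 and 3.75 and CD68 up by 4.06. Of 9 B cell markers 3 were higher and 4 lower (0.347; 0.619 with an estimated correlation), and TNFRSF13C had a log2 fold change of -1.44 and MZB1 one of 5.33, with a resting mean that rested largely on resting replicate 2, at 0.691 CPM. For this list camera and the median pointed down and fry pointed up. Of 4 platelet and red cell markers 2 were higher and 1 was lower (0.785; 0.881 with an estimated correlation), camera pointing down and fry and the median up.

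Among all annotated genes that met the rule, the largest increases were in ZBED2, FAM72B, POLQ, STIMATE, MT1G, CCL22 and CXCL9 beside GJB2, IL9 and CXCL10. ZBED2, a zinc finger transcription factor, had 1 count over all resting libraries and 229 CPM ± 73.2 in stimulated cells. The metallothionein MT1G (29.6 CPM ± 3.05) and the chemokines CCL22 (24.5 ± 17.2) and CXCL9 (20.5 ± 21.3) had whole counts throughout and 0 counts in every resting library, and were at least 826-fold, 690-fold and 577-fold higher. The CXCL9 mean rested largely on stimulated replicate 6, at 53.7 CPM. FAM72B, POLQ and STIMATE also had 0 counts in resting libraries, but their stimulated counts were not all whole, so their reads were shared with other features and their folds are uncertain. The same limit holds for CBS, NOS3, SLCO4A1, SLC6A9, SLC7A11, IFI44L, IFI27, CCNA2 and MZB1, which were near 0 in resting cells. The largest decreases were in P2RY11, FCRL6, PTGDR, WNT7A, LGR6, BAIAP3, CRIP2, PDZD4 and NHSL2 beside KLRF1. P2RY11 had 0 counts in every stimulated library and 21.9 CPM ± 4.74 in resting cells, at least 620-fold lower, with counts that were not whole in resting libraries. FCRL6 fell from 58.7 to 0.105 CPM and CRIP2 from 44.2 to 0.116 CPM, while the prostaglandin D2 receptor gene PTGDR had 2 counts and WNT7A 2 counts over all stimulated libraries, ratios of 0.00146 (0.000177 to 0.00528) and 0.00152 (0.000183 to 0.00548). Counts of FCRL6, PTGDR, LGR6, PDZD4 and NHSL2 were not whole in every library, so their folds are uncertain too.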

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

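The tests of admixture in resting replicate 5 were chosen after the library had been seen to stand apart; the other tests here were written before their results, although for the partial shift the direction of the outlying genes in that library had been seen and the correlation had not. In groups of 5 libraries, a value was singled out where its gap to the nearest library exceeded 0.71 of the group's range. This held for 27 of 247 gene values and 8 library measures, where chance gives about 12.8, and 12 of the 27 fell in resting replicate 5.

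In resting replicate 5, assembled loci held 22.29% of counts against 25.45% to 26.23% in the other resting libraries (gap over range 0.802). AARS1 was high there (1, at 4.01 CPM against 0 in the others), as were SH2D1A (0.967), FADS2 (0.859), IRF3 (0.791, 95.2 against 65.6 to 71.8 CPM), RNASEH2A (0.789, 7.7 against 2.95 to 3.95), TNFSF10 (0.785), ENO1 (0.734), NDUFA8 (0.734), SLC1A5 (0.733) and IFNAR1 (0.732, 23.1 against 7.84 to 11.9), and STIM1 was low (0.794, 140 against 201 to 217). Counts of AARS1 and SH2D1A were not whole in every library, so the assignment of shared reads could have set these outlying values. Stimulated cells or their RNA in this library would need a share of 19% to account for its assembled loci. Over 62 cell cycle genes the excess above the other resting libraries had a median of 0.71% of the stimulated level (quartiles 0.3% to 1.48%), which argues against such a mixture. A partial shift toward the stimulated pattern without entry into the cell cycle remains a candidate explanation: across genes outside that list, the library's deviations correlated with the fold change fitted without that donor at 0.399, against -0.124 to -0.03 for the other resting libraries, and genes are not independent replicates. The deviations of a gene cancel out over the resting libraries, so a positive correlation for 1 library lowers those of the others. The other libraries are thus no independent reference. Each deviation and its fold change also subtract the same resting libraries, which adds positive correlation. Whether such a partial shift arose in the donor, in culture or in handling was not tested. Without this library, 7425 features were higher and SLC7A1 ranked 30th among solute carriers.

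The larger share of assembled loci in resting cells was weighed against 2 technical explanations. Had reads of annotated genes gone to assembled loci in resting libraries, genes that share reads were predicted to show larger fold changes than others. The expression-matched difference in median log2 fold change was -0.313 (95% bootstrap interval -0.411 to -0.234, 4515 against 4808 genes), in the other direction. This does not decide the question, since a count that is not whole marks sharing with any feature. Reads placed wholly on an assembled locus would also leave a gene's count whole. A few dominant loci do not account for the larger share, since the 10 loci with the largest difference held 5.89% of the gap of 17.4 percentage points and 1000 loci held 73.4%. Unspliced or noncoding RNA retained in resting cells stays open and was not tested, since the positions of the loci were not used here. Because the groups differ in this share, scaling and state cannot be separated for small changes.

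In other libraries SLC7A1 was high in resting replicate 6 (0.77, 38 against 32 to 33.3 CPM), CRIP2 in resting replicate 6 (0.846), KLRG1 and ACTN1 in resting replicate 7 (0.773 and 0.724), MZB1 in resting replicate 2 (0.926, 0.691 against 0.121 to 0.163 CPM) and TYROBP in resting replicate 1 (0.72). STEEP1 was low in resting replicate 7 (0.836) and ZDHHC7 in resting replicate 1 (0.856). Among stimulated libraries, IL9 and IL5 were high in replicate 5 (0.809, 112 against 1.76 to 22.8 CPM, and 0.737, 22.7 against 0.761 to 6.52 CPM), TRIM22 in replicate 1 (0.822), ARG2 in replicate 2 (0.876), PSAT1 in replicate 7 (0.868) and H2AC18 in replicate 6 (0.713), and SURF4 was low in replicate 6 (0.793).

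The number of genes past the threshold was set against other splits of the 10 libraries. Of 100 splits drawn from 126, only the real one (1) gave as many, with 14816 features at the adjusted threshold in edgeR and 0 in the highest other split, 14 of the drawn splits parting all 5 pairs. At an unadjusted p under 0.05 the real split gave 15001 features and the highest other split 5690. Every other split put resting and stimulated libraries into both arms, so the difference between the groups widened the spread within them. Few adjusted calls could therefore arise there, and the comparison does not measure chance for this count. With the pairing by donor, exchange within pairs could not give a p under 0.0625, as for SLC7A1.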

How the results depend on the processing

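The alternatives with assembled loci removed, with whole-count genes alone and with the wider background were chosen after the data were seen. SLC7A1 stayed past the threshold in all alternatives that gave a value, with log2 fold changes from 2.14 to 2.83. It has no value among whole-count genes. Calls smaller than the shift between scalings rest on the scaling. In the paired fits with a replicate block, 7316 features were higher and 7657 lower in edgeR and 7734 and 8130 in DESeq2. With the block and the preset correlation, the interferon-stimulated list was at a camera adjusted p of 0.0395 in edgeR. It was at 0.0027 in DESeq2, where it had also passed without the block (0.0243). SAMHD1 came to an adjusted p of 0.0482 in edgeR and 0.0236 in DESeq2. Against the main fit, the block changed no other call of a named gene or list. Of the 14816 calls over all features, 14561 were shared with the paired edgeR fit. The rank of SLC7A1 among solute carriers was 37 with no filter, 21 with the filter at 5 CPM, 35 with DESeq2, 34 with DESeq2 and a replicate block and 22 with log2(TPM + 1). In the filter and DESeq2 fits the number of carriers compared differs.

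Counts of features moved by more than 1.5 times in few settings. Against a minimum log2 change of 1, 4512 were higher. With annotated genes alone, which are fewer, 4812 were higher and 4866 lower, 3226 and 3293 by at least 2-fold. With whole-count genes alone there were 2004 and 1964, and 1303 and 1317. Leaving out a library or a donor gave 6926 to 7425 higher and 7227 to 7629 lower.

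At the preset correlation, the camera adjusted p of the interferon-stimulated list was 0.0218 with no filter and 0.0243 with DESeq2. It was 0.00253 and 0.00185 with log2(TPM + 1) and log2(TPM + 0.1), and 0.0276 with annotated genes alone. When libraries or donors were left out, it was 0.0129 to 0.441. With an estimated correlation the calls were lost for T cell identity (0.158), ribosome biogenesis (0.188), unfolded protein response (0.504), early response (0.188), histones (0.158) and NK markers (0.209). The unfolded protein response list was at 0.144 among whole-count genes. With fry, which asks only whether the members move one way, the lists for cGAMP transport (4.45e-06), cGAS-STING (9.49e-07), interferon-stimulated genes (0.000769), amino acid transporters (9.66e-10), apoptosis (1.04e-06), activation (1.99e-05), solute carriers (3.29e-08) and monocyte markers (0.0276) passed, and the platelet list passed upward (0.00472). With assembled loci in the background, cGAS-STING (0.0238), interferon-stimulated genes (0.00204), amino acid transporters (0.00554), activation (0.033) and solute carriers (0.00302) passed and T cell identity (0.163) did not.

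Named genes that turned sign and passed in the main fit or in the alternative had log2 fold changes as follows. With upper-quartile factors LRRC8A was at -0.19. With total counts LRRC8A was at -0.25 and ZDHHC7 at -0.20. With log2(TPM + 1) and log2(TPM + 0.1), LRRC8B was at -0.0708 and -0.0845, LRRC8A at -0.38 and -0.40, IRF3 at -0.0555 and -0.0559, RELA at -0.27 and -0.27 and ZDHHC7 at -0.30 and -0.31. With annotated genes alone ABCC1 was at -0.0340, LRRC8B at -0.30, LRRC8D at -0.46, LRRC8A at -0.60, ZDHHC3 at -0.20, IRF3 at -0.16, RELA at -0.46 and ZDHHC7 at -0.54. With whole-count genes alone LRRC8A was at -0.76, DNASE2 at -0.0878, TBK1 at -0.12, TOLLIP at -0.12, ZDHHC3 at -0.36 and ZDHHC7 at -0.70. The shift of all fold changes between these scalings accounts for such turns by construction, except for IRF3 with TPM, where that shift alone would have left it above 0; the cause there and of the other changes was not tested. Beyond these, named genes lost a call in 37 fits of single genes and gained one in 27. In the other 3636 the call stayed the same, and these include turns of sign where the gene passed in neither fit. Among such genes, over the alternatives, SAMHD1 went down to -0.23 and IKBKE up to 0.12.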

Other observations

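The gene families here were chosen after the data were seen, and their tests with them; the test of read sharing was written before its result. Several gene families were mostly higher, some of whose members also stood in the fixed lists. All 42 proteasome genes were higher in stimulated cells, with a median log2 fold change of 2.36 (camera adjusted p over 14 families = 3.57e-20; adjusted p = 0.0798 with an estimated correlation). All 8 subunits of the cytosolic chaperonin, which folds actin and tubulin, were higher with a median of 3.37 (2.21e-08; 0.0844), as were 73 of 74 mitochondrial ribosomal proteins with a median of 2.41 (1.16e-15; 0.0844), all 20 aminoacyl-tRNA synthetases with a median of 2.48 (5.35e-08; 0.0844) and all 6 metallothioneins, which bind zinc and copper, with a median of 4.07 (0.00418; 0.0844). Of 30 kinesins 24 were higher and 3 lower (5.86e-05; 0.0658), and of 12 tubulins 9 were higher and 2 lower (0.00119; 0.0844). No family passed with an estimated correlation, the second value in each bracket.

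Cytosolic ribosomal proteins did not follow the mitochondrial ones or the ribosome biogenesis genes. Of 82 tested, 13 were higher and 45 lower, with a median of -0.19 (adjusted p = 0.000145; 0.488 with an estimated correlation), and with assembled loci removed before scaling 6 were higher and 74 lower. ZNF zinc finger genes were lower for 215 and higher for 98 of 439, with a median of -0.46 (5.35e-08; 0.0658), and with assembled loci removed 49 were higher and 293 lower. Of 18 integrins 5 were higher and 8 lower (0.0443; 0.0844). Chemokines (6 higher and 3 lower of 13; 0.546; 0.733), GIMAP GTPases (3 and 2 of 8; 0.546; 0.836) and dual-specificity phosphatases (6 and 6 of 17; 0.061; 0.137) did not pass. HLA class II genes were higher for 5 of 12 and lower for 0, with a median of 1.17 while camera pointed down (0.806; 0.875).

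For annotated genes near 0 in resting cells and high in stimulated ones, read sharing was the only explanation tested. Of 75 genes under 0.5 CPM in resting and at least 20 CPM in stimulated cells, 52% had counts that were not whole in a stimulated library, against 56.8% of 6870 other genes at that stimulated level. The odds ratio over 3 strata of level was 0.716 (exact 95% interval 0.441 to 1.17), so an excess of read sharing was not shown for the set and could not be excluded within that interval. Cell cycle genes with whole counts, such as KIF20A, showed no sharing by this measure. Reads placed wholly on another feature would also leave a count whole, so misplaced reads are not excluded for them. For AARS1, SH2D1A, CBS, POLQ, FAM72B and STIMATE, whose reads were shared, induction and assignment of reads to another feature cannot be told apart here.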
